A study of Mus musculus with 4 samples.

How the data were processed

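RNA from mouse mammary tissue was measured on 4 Affymetrix arrays, 2 from animals labelled wild-type (WT) and 2 from animals labelled knockout (KO) for STAT5, a transcription factor activated by prolactin and growth hormone. Per the series' design text, 2 mice of each genotype were sampled, so the arrays were taken as separate animals. The same text gives a time of 6 days without naming the event it is counted from. Per the labels, total RNA was extracted with TRIzol and labelled with biotin by the standard Affymetrix protocol. Genotype was taken from the labels. Replicates were numbered within a genotype in the order of deposit, so equal numbers do not pair animals.

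The deposited values are probe set intensities on a linear scale, made with MAS5 per the submitters' processing notes. The version and settings of MAS5 were not given in the sources used here. On each array the mean signal after leaving out the lowest and highest 2% of probe sets was 500, so the authors' values carry a common scaling, as read from the values. Detection calls were not used here, so a dim signal could not be placed above or below background. Median signals were 131 and 131 on WT replicates 1 and 2, and 121 and 124 on KO replicates 1 and 2. The number of arrays limits the precision.

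The array held 45101 probe sets, of which 64 were controls and were left out. Of the other 45037 probe sets, 34945 had 1 gene symbol, 932 had several and 9160 are unnamed here. Symbols came from the platform annotation, which can be old, and were checked through Entrez identifiers, which were found for 34741 named probe sets. No symbol changed in this update. No gene was named from a probe set with several symbols. A gene was represented by its probe set with the highest mean log2 value over the 4 arrays. No genome build is named for the array, so no coordinates are given.

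Signals were transformed as log2(signal + 16), and log2 differences between KO and WT refer to this scale, which understates the change of dim genes. Probe sets whose mean log2 value was at or above the median of all probe sets were tested, which set the limit at 7.15 on the log2 scale (a signal of 126) and left 22519 probe sets and 11360 genes. KO was compared with WT by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend in the variance), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05 on the adjusted p. Each probe set leaves 2 residual degrees of freedom, and the model borrows strength across probe sets. The p-values measure only the spread between these samples. An exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.333, so none was used.

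Gene lists were compared with all other tested genes by camera in limma, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 24 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance and makes no comparison with other genes, were run as alternatives. With an estimated correlation camera rests here on 2 residual degrees of freedom and has little power. Milk and secretory genes had an estimated correlation of -0.022 and a camera p of 3.31e-06 at the preset one. Their adjusted p was still 0.562 with the estimate. Failing this test is therefore not counted against a list by itself. For some other lists the estimate lay far above the preset 0.01. It was 0.865 for cell cycle genes, 0.903 for skeletal muscle, 0.821 for general epithelial markers and 0.652 for cholesterol synthesis. For such lists the camera p at the preset correlation can be far too small. Low power and genes that vary together cannot be told apart there. The lists were the STAT family, STAT5 target and feedback genes, mammary alveolar regulators, milk and secretory genes, cell cycle genes, fatty acid and triglyceride synthesis, cholesterol synthesis, interferon response, MHC class II genes, and immediate early and stress genes. Lists of cell type markers covered luminal progenitor, hormone-sensing luminal, general epithelial, basal and myoepithelial cells, adipocytes, brown adipocytes, fibroblasts and matrix, endothelium, macrophages, B cells, T cells, plasma cells, skeletal muscle and red blood cells. Within each list, p-values were also adjusted over the list alone.

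The tests, the lists and the rule for named genes were fixed before the data were examined. The rule names Stat5a and Stat5b, then the 12 genes with the largest fall and the 12 with the largest rise among those past the threshold whose KO arrays both lay on the same side of both WT arrays. From each list it adds up to 4 members past the threshold with the smallest p, or, where none passed, up to 2 members with the largest absolute difference. Genes named outside this rule are said to have been chosen after their values were seen.

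Alternatives were a pseudocount of 1 or 64, quantile normalization, centring each array on its median, no filter, a filter at the 75th percentile, eBayes without the trend, the mean of all probe sets of a gene, and leaving out each array in turn, where the lone array was assumed to vary like the other genotype. Centring on the general epithelial markers, leaving the skeletal muscle list out of the count, and an estimated correlation under each other setting were added after the data were seen. The fit was tested on simulated data with 22519 probe sets, 200 of them changed in each of 5 runs, besides a list shifted to try camera. It called 0.4% of changes of 1.5-fold, 22.8% of 2-fold, 87.2% of 4-fold and 100% of 8-fold changes, and 4.19% of its calls were false. The simulated errors were independent and drawn from the fitted variance model. These shares therefore do not cover genes that vary together or a differing mix of tissues. Figures were drawn with matplotlib 3.10.9, with pandas 2.3.3 and numpy 2.4.6.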

Results

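Transcript levels were measured in mammary tissue of mice labelled WT or KO for STAT5, on 2 arrays per genotype, each from a separate mouse per the design text. The title of the series places the comparison in the development of luminal progenitors, the epithelial cells that give rise to the milk-secreting alveoli. The arrays were alike in technical measures. The 3'/5' signal ratio of actin ran from 1.12 to 1.21 and that of Gapdh from 0.771 to 0.799 over the 4 arrays. Across probe sets, which are not independent replicates, Pearson's r was 0.981 between the WT arrays, 0.980 between the KO arrays and 0.968 to 0.973 between genotypes. Of the tested probe sets, 248 differed by more than 2-fold between the WT arrays and 441 between the KO arrays, against 951 to 1381 for a KO with a WT array.

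Stat5a and Stat5b, the neighbouring genes that encode STAT5, still gave signals on both KO arrays. The brighter Stat5a probe set stood at 2307 and 2061 on the WT arrays and at 1836 and 861 on KO replicates 1 and 2, which is 84.1% and 39.4% of the WT mean. Its log2 difference was -0.79 with an SE of 0.32 (limma adjusted p = 0.246), and its other probe set gave -1.22 (adjusted p = 0.106). The brighter Stat5b probe set stood at 1522 and 1506 on the WT arrays and at 1069 and 712 on the KO arrays, a log2 difference of -0.78 with an SE of 0.21 (limma adjusted p = 0.102), and its other probe set gave -0.97 (adjusted p = 0.121). All 4 probe sets were lower on both KO arrays than on both WT arrays, and none passed the threshold. Without KO replicate 1, Stat5a passed at -1.33 (adjusted p = 0.0115) and Stat5b at -1.07 (adjusted p = 0.0227). The labels do not say which gene or which part of it was deleted, so a probe set outside that part would not check the genotype. In the STAT family list 5 members were tested, 0 passed in either direction over all genes, and 0 higher and 1 lower passed when adjusted over the list alone (median log2 difference -0.30, camera adjusted p = 0.101). The median ranged from -0.35 to -0.07 with an array left out. The list passed without KO replicate 1 (camera adjusted p = 0.00677), but with an estimated correlation no list passed there (smallest adjusted p = 0.731).

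Transcripts of 3 caseins fell to 1.40% of the WT level or less, and Ltf rose. Csn1s1, Csn2 and Ltf had the 3 smallest adjusted p of all tested genes. Csn1s1, which encodes alpha-s1-casein, fell from a signal of 10649 ± 531 to 36.3 ± 1.10 (SD, n = 2), or 0.341% of the WT level. Csn2, the gene of beta-casein, fell to 1.08% and Csn1s2a, another calcium-sensitive casein, to 1.40% of the WT level. The KO signals of Csn1s1 and Csn1s2a lay below the KO array medians of 121 and 124. Those of Csn2, at 122 and 83.3, lay near and below them. Background may therefore set the percentages of all 3. Ltf, which encodes the iron-binding milk and secretion protein lactotransferrin, rose from 454 ± 14.0 to 6255 ± 859 (SD, n = 2). The log2 differences were -7.67 for Csn1s1 (limma adjusted p = 8.99e-06), -6.35 for Csn2 (adjusted p = 8.91e-05), -5.72 for Csn1s2a (adjusted p = 0.00594) and 3.73 for Ltf (adjusted p = 0.000313). Csn1s1, Csn2 and Ltf stayed past the threshold in every setting, including those that left out an array. Csn1s2a did so where it was tested, which leaves out the 75th percentile filter and the mean of all probe sets.

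**Figure D1:**
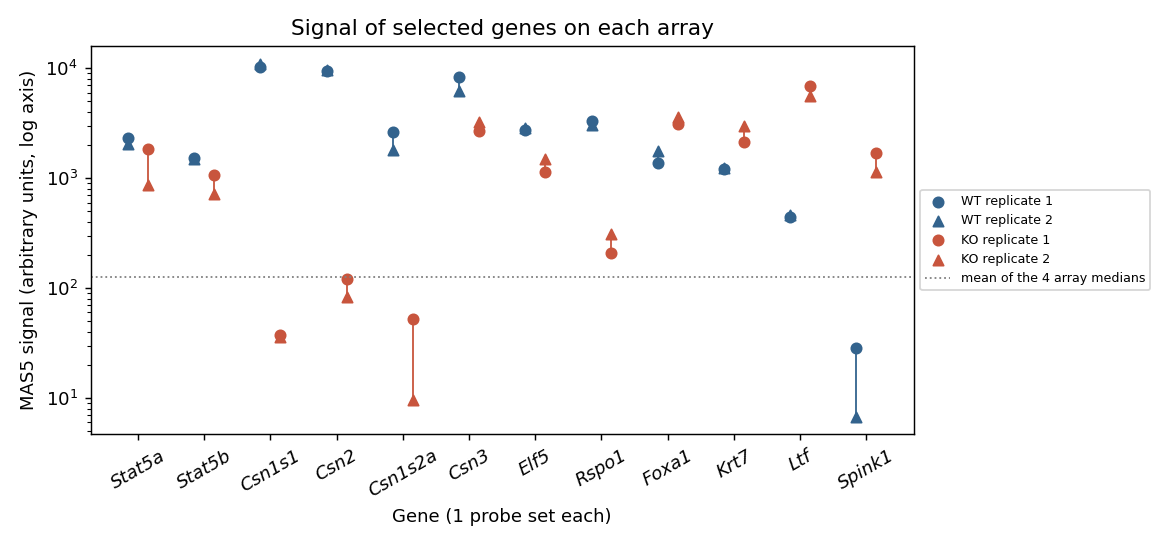
MAS5 signal (arbitrary units, log axis) of 12 genes on each array, with circles and triangles for replicates 1 and 2 of WT (blue) and KO (red) and a dotted line at the mean of the 4 array medians. Csn1s1 stands at 10274 and 11025 on the WT arrays and at 37.1 and 35.6 on the KO arrays, whereas the mean of Ltf goes from 454 to 6255 and the signals of Stat5a on the KO arrays lie far apart, at 1836 and 861.

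In all, 292 genes passed the threshold, 138 higher and 154 lower in KO, represented among 450 probe sets (215 higher, 235 lower). KO and WT arrays did not overlap for 53.7% of all tested genes, where chance gives 33.3%. Changes of at least 2-fold numbered 137 lower and 98 higher. Falls of at least 8-fold were seen in 11 genes and rises of this size in 6. The count moved to 100 genes without WT replicate 1, to 43 without WT replicate 2 and to 601 without KO replicate 2. Of the calls 47.3% were higher in KO, against 61.7% after centring each array on its median and 79.2% after centring on epithelial markers, which moved the median difference of all genes from -0.01 to 0.39.

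**Figure D2:**
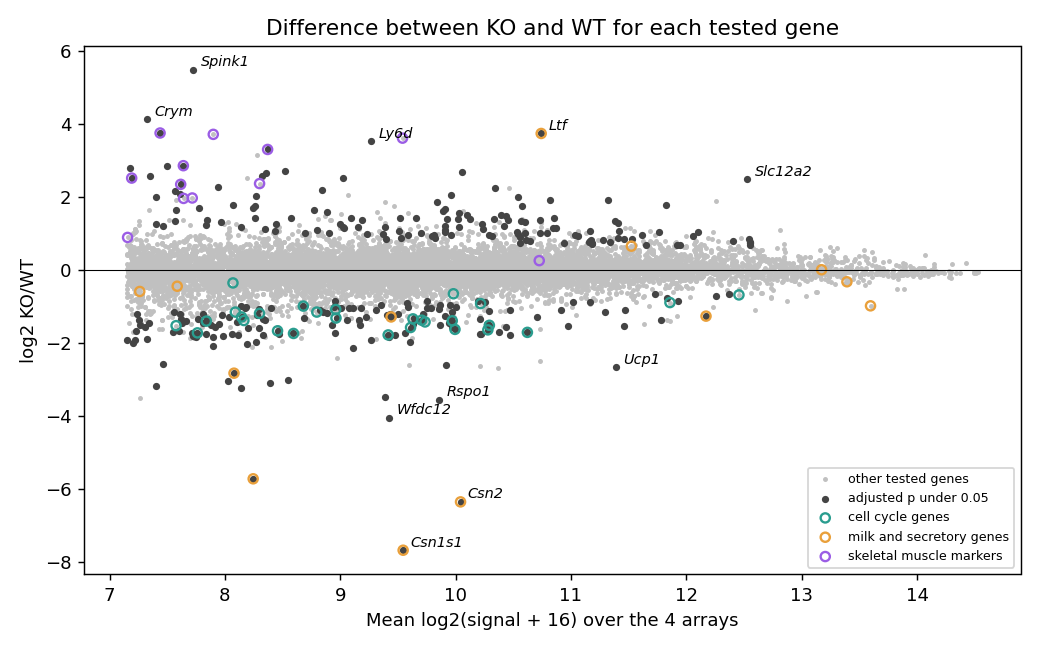
Log2 KO/WT against the mean log2(signal + 16) over the 4 arrays for each of the 11360 tested genes, with genes past an adjusted p of 0.05 in black and members of 3 gene lists ringed in colour. Csn1s1 and Csn2 lie lowest at -7.67 and -6.35, and the medians of cell cycle genes and skeletal muscle markers lie at -1.38 and 2.44.

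After the caseins, the largest falls among genes past the threshold were those of Wfdc12, Rspo1 and Gjb2. Wfdc12, a member of the whey acidic protein family, fell by 4.05 on the log2 scale (limma adjusted p = 0.000936). Rspo1, a secreted enhancer of Wnt signalling, fell by 3.56 (adjusted p = 0.00144), from 3181 ± 226 to 259 ± 69.8 (SD, n = 2). Gjb2, a gap junction protein, fell by 3.49 (adjusted p = 0.00248), Atp6v1c2, a subunit of the vacuolar proton pump, fell by 3.24 (adjusted p = 0.00594), and Atp7b, a copper transporter, fell by 3.18 (adjusted p = 0.00464). Col9a1, a collagen chain, changed by -3.09 (adjusted p = 0.0124), Hepacam2 by -3.04 (adjusted p = 0.00215), Tph1, which makes the rate-limiting enzyme of serotonin synthesis, by -3.02 (adjusted p = 0.0224) and Btn1a1, the milk fat globule protein butyrophilin, by -2.83 (adjusted p = 0.00267). Col9a1 lost its call without WT replicate 2 and both Col9a1 and Tph1 lost theirs with no filter, whereas Wfdc12, Rspo1 and Gjb2 kept theirs in every setting. Atp6v1c2, Atp7b, Hepacam2 and Btn1a1 lost no call where they were tested, but none was tested with the 75th percentile filter, nor Atp7b and Btn1a1 with the mean of all probe sets, nor Atp7b with a WT array left out.

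Milk and secretory genes were lower as a group. Of 13 members tested, 6 fell, 1 rose and 6 did not pass over all genes, and 7 lower and 2 higher passed when adjusted over the list alone. The median log2 difference was -0.98 (camera adjusted p = 1.98e-05; adjusted p = 0.562 with an estimated correlation). The median was -0.57 without KO replicate 1, -1.30 without KO replicate 2, -0.57 with no filter, which leaves 24 members, -0.59 with the mean of all probe sets and -0.58 centred on epithelial markers. The list also passed with fry (adjusted p = 0.0255), as no other list did. Csn3, the gene of kappa-casein, fell by 1.27 (limma adjusted p = 0.0321) and stood at 41.2% of its WT level, against 0.341% to 1.40% for the other 3 caseins. Its call was lost with either WT array left out, with no filter, with no trend, with the mean of all probe sets and centred on epithelial markers. General epithelial markers, with a median of -0.45, moved the same way as this list and the next.

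Luminal progenitor markers moved in both directions. Of 13 tested, 3 fell (Rspo1, Csn3 and Elf5), 1 rose (Ltf) and 9 did not pass, and 8 lower and 2 higher passed when adjusted over the list alone. The median was -0.85 (camera adjusted p = 0.0131; adjusted p = 0.562 with an estimated correlation). Ltf, Csn3 and Wfdc18 also stand in the milk list. Elf5, an ETS transcription factor needed for alveolar development, fell by 1.10 (limma adjusted p = 0.0324), from 2811 ± 78.0 to 1314 ± 238 (SD, n = 2). The number that fell ranged from 1 to 6 with an array left out. The calls of Elf5 and Csn3 were lost with either WT array left out, with no filter, with no trend and centred on epithelial markers, and those of Ltf and Rspo1 were kept in every setting.

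Among mammary alveolar regulators 2 of 15 tested members fell, Elf5 and Ehf, another ETS factor of epithelial cells (-1.78, limma adjusted p = 0.0435). The other 13 did not pass, 1 higher and 5 lower passed when adjusted over the list alone, and the list did not pass (median -0.25, camera adjusted p = 0.0737). The median was -0.08 without WT replicate 1 (camera adjusted p = 0.0607) and -0.17 without KO replicate 1 (adjusted p = 0.343). The list passed without WT replicate 2 (camera adjusted p = 0.0449), without KO replicate 2 (0.00753), with the 75th percentile filter (0.0142), with the mean of all probe sets (0.0159) and centred on epithelial markers (0.0266), though no list passed in any setting with an estimated correlation (smallest adjusted p = 0.407). Of 16 STAT5 target and feedback genes, Elf5 fell and 15 did not pass, with 1 higher and 5 lower when adjusted over the list alone (median -0.30, camera adjusted p = 0.0737). The median was -0.15 without KO replicate 1 (camera adjusted p = 0.0959) and -0.15 without WT replicate 2 (adjusted p = 0.0853). This list passed without WT replicate 1 (camera adjusted p = 0.0372), without KO replicate 2 (0.00880), with no filter (0.0416) and centred on epithelial markers (0.00203), again only at the preset correlation. Hormone-sensing luminal markers split. Foxa1, a cofactor of the oestrogen receptor, rose by 1.08 (limma adjusted p = 0.0369) and Cited1, a transcriptional coregulator, fell by 2.59 (adjusted p = 0.0381), 8 of 10 did not pass, and 4 higher and 3 lower passed when adjusted over the list alone (median -0.14, camera adjusted p = 0.974, and 0.0425 when centred on epithelial markers; 0.407 there with an estimated correlation). The calls of Elf5, Ehf, Foxa1 and Cited1 were lost without WT replicate 1, without WT replicate 2, with no filter and with no trend, and that of Elf5 also centred on epithelial markers and that of Ehf with the 75th percentile filter and the mean of all probe sets.

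General epithelial markers were slightly lower as a group. Of 23 tested, Ehf fell, Krt7, a keratin of simple epithelia, rose by 1.02 (limma adjusted p = 0.0484), and 21 did not pass, whereas 10 lower and 2 higher passed when adjusted over the list alone. The median was -0.45 (camera adjusted p = 0.00316; adjusted p = 0.562 with an estimated correlation), with -0.68 on KO replicate 1 and -0.18 on KO replicate 2 against the WT mean. Without KO replicate 1 the list no longer passed (median -0.18, camera adjusted p = 0.332), and without KO replicate 2 10 members fell. Of 16 basal and myoepithelial markers, the oxytocin receptor gene Oxtr fell by 0.89 (limma adjusted p = 0.0425; -0.52 for its other probe set) and 15 did not pass, with 1 higher and 1 lower when adjusted over the list alone (median -0.25, camera adjusted p = 0.0737). The basal list passed without WT replicate 1 (camera adjusted p = 0.0178), without KO replicate 2 (0.000519) and with the 75th percentile filter (0.0458), in each case only at the preset correlation (adjusted p = 0.557 or more with an estimated one). Ehf, Krt7 and Oxtr lost their calls with either WT array left out, with no filter, with no trend and with the mean of all probe sets. Ehf and Krt7 also lost theirs with the 75th percentile filter, Krt7 after quantile normalization, and Oxtr without KO replicate 1 and centred on epithelial markers.

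Cell cycle genes were lower in KO. All 28 tested members lay lower on both KO arrays than on both WT arrays, in the values as deposited. Of these 14 fell and 14 did not pass over all genes, 27 lower and 0 higher passed when adjusted over the list alone, and the median was -1.38 (camera adjusted p = 1.55e-20; adjusted p = 0.562 with an estimated correlation). The replication helicase subunits Mcm6 and Mcm5 fell by 1.71 (limma adjusted p = 0.0184) and 1.64 (adjusted p = 0.0236). Top2a, a topoisomerase of dividing cells, fell by 1.63 (adjusted p = 0.0308), but by 0.58 for its other probe set and with no call for the mean of all probe sets, and the mitotic checkpoint kinase gene Bub1 fell by 1.72 (adjusted p = 0.0324). Without WT replicate 2 the median was -1.04 and 0 members passed over all genes, without KO replicate 2 24 passed, and after centring on epithelial markers the median was -0.98 and 2 members passed. The number that passed was 0 with no filter, 4 with no trend, 5 with the 75th percentile filter, 5 with the mean of all probe sets and 8 with median centring. These 4 named genes lost their calls with no filter, without WT replicate 2 and centred on epithelial markers. General epithelial markers, with their median of -0.45, moved the same way, and skeletal muscle markers, with a median of 2.44, the opposite way.

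Genes of cholesterol synthesis were also lower. Of 14 tested, Sqle, which encodes squalene epoxidase, fell by 1.75 (limma adjusted p = 0.0203), 13 did not pass, and 7 lower and 0 higher passed when adjusted over the list alone. The median was -0.87 (camera adjusted p = 2.32e-05; adjusted p = 0.562 with an estimated correlation), with -0.42 on KO replicate 1 and -1.29 on KO replicate 2. Without KO replicate 1, 10 of the 14 fell. Among 20 genes of fatty acid and triglyceride synthesis, the desaturase gene Fads2 fell by 1.34 (limma adjusted p = 0.0138) and 19 did not pass, with 1 lower and 0 higher when adjusted over the list alone (median -0.18, camera adjusted p = 0.0737). Without KO replicate 1 this list passed (median -0.30, camera adjusted p = 4.46e-05; adjusted p = 0.731 with an estimated correlation) and 6 members fell. It also passed without WT replicate 2 (camera adjusted p = 0.00477), with the 75th percentile filter (0.0343), with the mean of all probe sets (0.0159) and centred on epithelial markers (0.0266), in each case only at the preset correlation. Its median ranged from -0.34 to -0.02 with an array left out. Both genes lost their calls without WT replicate 2, Fads2 also without WT replicate 1 and centred on epithelial markers, and Sqle with no filter.

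The largest rise among genes past the threshold was that of Spink1, a secreted trypsin inhibitor. Its signals were 28.3 and 6.78 on the WT arrays and 1697 and 1142 on the KO arrays (log2 difference 5.47, limma adjusted p = 0.00248). Crym, a thyroid hormone binding protein, rose by 4.12 (adjusted p = 0.0314) and Ly6d, a surface protein, by 3.51 (adjusted p = 0.0118). Trim34a rose by 2.85 (adjusted p = 0.00594), the agouti signalling gene a by 2.79 (adjusted p = 0.0134), the arginase gene Arg1 by 2.69 (adjusted p = 0.0124), Tox2 by 2.69 (adjusted p = 0.0159) and Fam25c by 2.64 (adjusted p = 0.0172). With no filter the calls of Spink1 and Trim34a were kept and those of the other 6 genes were lost. Spink1, Trim34a, Crym and a were not tested with the 75th percentile filter or with a KO array left out, being too dim there. Crym and a were also not tested with a pseudocount of 1, nor Arg1 and Fam25c with the 75th percentile filter. The labels name no mouse strain. Crym lost its call without WT replicate 1, and Fam25c and a without WT replicate 2.

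Genes of skeletal muscle, a tissue that lies against the mammary gland, also rose. Tnni2 rose by 3.75 (limma adjusted p = 0.0472), the fast myosin gene Myh4 by 3.30 (adjusted p = 0.0138), Tnnc2 by 2.85 (adjusted p = 0.0297), Myh1 by 2.51 (adjusted p = 0.0395) and Pvalb by 2.34 (adjusted p = 0.0451). Of 12 skeletal muscle markers tested, 5 rose, 0 fell and 7 did not pass, and 11 higher and 0 lower passed when adjusted over the list alone. The median was 2.44 (camera adjusted p = 6.43e-10; adjusted p = 0.562 with an estimated correlation), with 2.92 on KO replicate 1 and 2.06 on KO replicate 2. With the filter at the 75th percentile 2 members were left and the list did not pass (median 1.93, camera adjusted p = 0.121). Without WT replicate 2 the calls of Myh4, Tnnc2, Myh1 and Pvalb were lost, and that of Pvalb also without WT replicate 1. Tnni2 lost its call after quantile normalization and without the trend and was not tested with a KO array left out, and all 5 calls were lost with no filter. Those of Myh1 and Pvalb were also lost with no trend, and that of Pvalb with the mean of all probe sets. Myh1 was likewise not tested with a KO array left out, nor were Tnnc2 and Pvalb without KO replicate 1. With an array left out the number of markers tested ranged from 5 to 14 and the median from 1.88 to 3.01.

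Interferon response genes were higher and MHC class II genes lower. Of 19 interferon response genes 1 rose, Oasl2 (1.01, limma adjusted p = 0.0481), 0 fell and 18 did not pass, with 7 higher and 0 lower when adjusted over the list alone. The median was 0.52 (camera adjusted p = 7.05e-06; adjusted p = 0.562 with an estimated correlation). Of 7 MHC class II genes, all lower on both KO arrays in the values as deposited, 1 fell, the beta chain gene H2-Eb1 (-0.70, limma adjusted p = 0.0437), and 6 did not pass, with 5 lower and 0 higher when adjusted over the list alone. The median was -0.64 (camera adjusted p = 5.32e-05; adjusted p = 0.562 with an estimated correlation). The value of H2-Ea, named after its values were seen, was -3.50 (limma adjusted p = 0.262) and rested on WT replicate 1 alone, with 3391 there against 62.5 on WT replicate 2. B cell markers, of which 13 could be compared with no filter, moved the same way (median -0.78). H2-Eb1 lost its call whichever array was left out, and Oasl2 with either WT array or KO replicate 1 left out. Both lost it with no filter and with no trend, and H2-Eb1 also with median centring, with the 75th percentile filter and centred on epithelial markers.

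Macrophage markers stood close to the threshold. Of 14 tested 0 passed over all genes, 3 higher and 0 lower passed when adjusted over the list alone, and the median was 0.16 (camera adjusted p = 0.0388; adjusted p = 0.562 with an estimated correlation). Cd163, a scavenger receptor of macrophages, gave 1.07 (limma adjusted p = 0.0507) and C1qc 0.65 (adjusted p = 0.123). The list passed with no filter (camera adjusted p = 0.0166), with the 75th percentile filter (0.0142) and with the mean of all probe sets (0.0161), each only at the preset correlation. The median was 0.07 without WT replicate 2, 0.10 without KO replicate 1, 0.25 without KO replicate 2 and 0.27 without WT replicate 1. The list did not pass without KO replicate 1 (camera adjusted p = 0.146), without WT replicate 2 (0.130), after quantile normalization (0.0551), after median centring (0.0505) or after centring on epithelial markers (0.0953).

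Brown adipocyte markers were lower relative to other genes. Centred on epithelial markers, which moved the median of all genes to 0.39, their median was 0.18 and the list still passed as lower at the preset correlation (camera adjusted p = 0.00047; adjusted p = 0.407 with an estimated correlation). Ucp1, the uncoupling protein of brown fat, fell by 2.66 (limma adjusted p = 0.0228), with signals of 4614 and 9828 on the WT and 1038 and 1066 on the KO arrays. Its call was lost with no filter. It was the only called member of 9, 8 did not pass, and 4 lower and 0 higher passed when adjusted over the list alone. The median was -0.22 (camera adjusted p = 0.00853; adjusted p = 0.562 with an estimated correlation), and the list did not pass without KO replicate 1 (-0.03, camera adjusted p = 0.178), whereas its median was -0.67 without KO replicate 2. Of 15 general adipocyte markers 0 passed, over all genes or adjusted over the list alone (median 0.15, camera adjusted p = 0.209, and 0.0279 with the mean of all probe sets; 0.502 there with an estimated correlation). The values were 1.88 for Pck1 (limma adjusted p = 0.206) and -0.76 for Lep (adjusted p = 0.60). The WT arrays lay far apart for Pck1, at 1061 and 5999, against 7943 and 11065 on the KO arrays.

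Stromal, vascular and blood cell lists did not pass, though some did in other settings. Of 14 fibroblast and matrix markers Thbs2 rose by 0.99 (limma adjusted p = 0.0455), 13 did not pass, and 1 higher and 0 lower passed when adjusted over the list alone (median 0.08, camera adjusted p = 0.187). The median ranged from 0.0055 to 0.12 with an array left out. The call of Thbs2 was lost with either WT array left out, after quantile normalization, with no filter, with the 75th percentile filter, with no trend and with the mean of all probe sets. Of 12 endothelial markers 0 passed over all genes and 2 higher and 0 lower when adjusted over the list alone (median 0.13, camera adjusted p = 0.0737), with 0.73 for Flt1 (limma adjusted p = 0.0896; 0.31 to 0.53 for its other 3 probe sets) and 0.54 for Robo4 (adjusted p = 0.102). The endothelial median ranged from 0.0053 to 0.22 with an array left out. The endothelial list passed without KO replicate 2 (camera adjusted p = 0.00753) and with no filter (0.0431), but not with an estimated correlation (adjusted p = 0.557 and 0.595). Most blood cell markers were too dim to be tested. The only tested B cell marker, Blnk, gave -0.36 (limma adjusted p = 0.334, list camera adjusted p = 0.318) and did not pass alone either. Of 2 T cell markers 0 passed over all genes and 1 lower when adjusted over the list alone (median -0.94, camera adjusted p = 0.149), with -1.21 for Cd3e (limma adjusted p = 0.514) and -0.66 for Lat (adjusted p = 0.147). The median of T cell markers ranged from -1.64 to -0.23 and that of B cell markers from -0.63 to -0.18 with an array left out. With no filter, 13 B cell markers (median -0.78, camera adjusted p = 0.000324) and 12 T cell markers (median -0.75, camera adjusted p = 0.000252) passed as lower at the preset correlation, with 0 members past the threshold singly. With an estimated correlation neither passed there (adjusted p = 0.558 and 0.542). The T cell list also passed without KO replicate 2 (camera adjusted p = 0.0381) and centred on epithelial markers (0.0184), again not with an estimated correlation (adjusted p = 0.557 and 0.407).

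Of 4 plasma cell markers 0 passed over all genes and 1 higher and 0 lower when adjusted over the list alone (median 0.05, camera adjusted p = 0.793), with 1.74 for Irf4 (limma adjusted p = 0.0954) and -0.79 for Ighm (adjusted p = 0.243; -2.02 to -1.21 for its other 3 probe sets). Irf4 stood at 383 and 358 on the WT arrays and far apart, at 741 and 2178, on the KO arrays. The only tested red blood cell gene, Alas2, gave 0.43 (limma adjusted p = 0.465, list camera adjusted p = 0.414), ranged from 0.04 to 0.83 with an array left out and did not pass alone. Of 13 immediate early and stress genes, the heat shock gene Hspa1b rose by 0.83 (limma adjusted p = 0.0369) and 12 did not pass, with 3 higher and 0 lower when adjusted over the list alone (median 0.16, camera adjusted p = 0.101, and 0.0115 without KO replicate 1; 0.731 there with an estimated correlation). The median ranged from 0.05 to 0.27 with an array left out. The call of Hspa1b was lost with either WT array or KO replicate 1 left out, with no filter, with no trend and centred on epithelial markers.

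**Figure D3:**
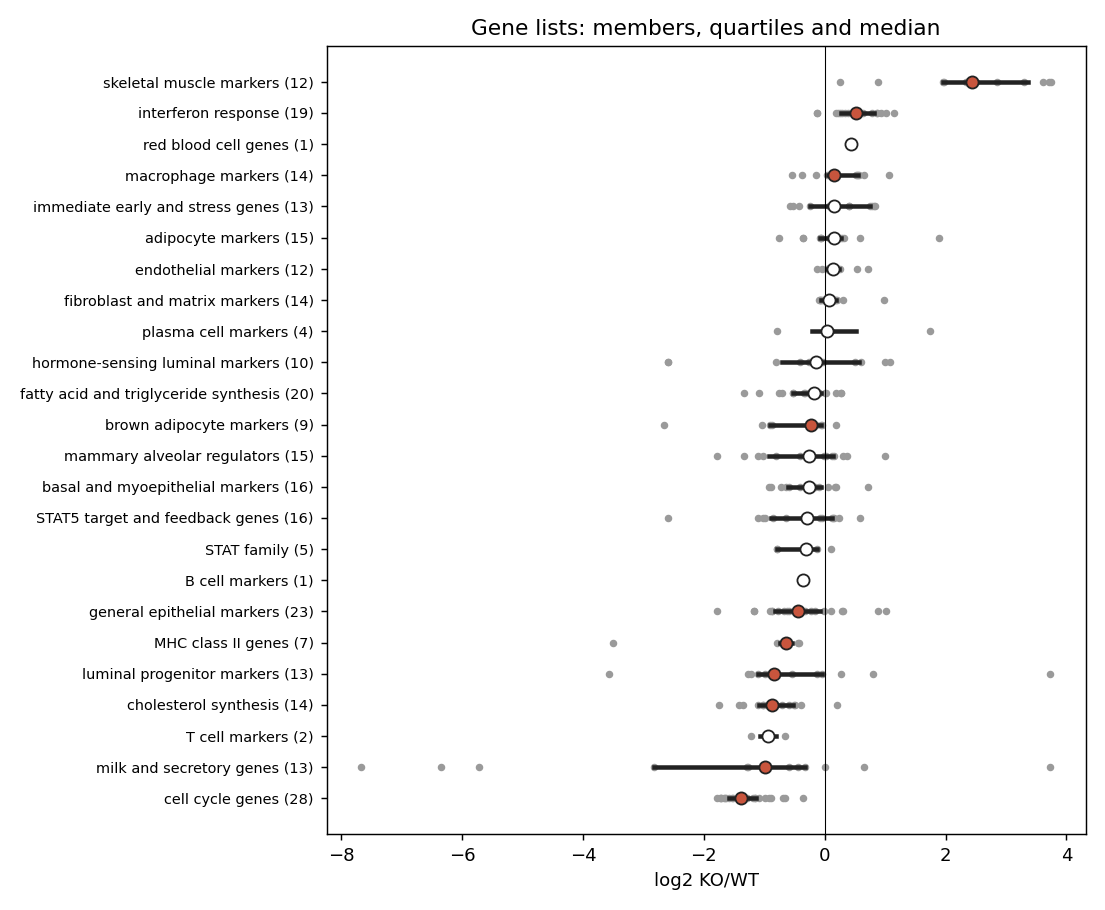
Log2 KO/WT of the tested members of 24 gene lists (grey points, number tested in brackets), with a bar over the middle quartiles and a dot at the median, filled red where the camera adjusted p is under 0.05. Cell cycle genes have the lowest median at -1.38 and skeletal muscle markers the highest at 2.44, and 10 of the 24 lists pass, 3 higher and 7 lower, against 0 with an estimated correlation (smallest adjusted p = 0.562) and 1 with fry. The estimated correlation gives little power with 2 residual degrees of freedom, and the preset one can make p too small for lists whose genes vary together.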

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

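Centring on epithelial markers was chosen after the data were seen. The count of genes, 292 as reported, was 27 with no filter, 127 with the 75th percentile filter and 137 with no trend, and ranged from 43 to 601 with an array left out. That of probe sets, 450 as reported, was 38, 182 and 205 in the same settings and ranged from 67 to 1021. The filters change how many probe sets are adjusted over and also which ones enter the variance model. A left-out array leaves fewer samples, with the spread taken from the genotype that keeps both arrays. Which of these moved the counts was not tested. For the trend and for fry the cause was not tested either. Camera with an estimated correlation has little power with 2 residual degrees of freedom, so its losses do not count against a list. The 10 lists past the threshold became 0 with an estimated correlation, also under each other setting (a combination chosen after the data were seen), and 1 with fry. The log2 difference of Stat5a ranged from -1.33 to -0.25 and that of Stat5b from -1.07 to -0.50 with an array left out, both past the threshold only without KO replicate 1.

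Of 56 named genes besides Stat5a and Stat5b, 44 passed and kept their direction wherever tested, and 30 of them lost their call with no filter. Only 24 of the 44 could be tested in every setting, the others being too dim in some, and 6 of the 24 always passed. Of 35 tested without each array 15 always passed. Values that did not pass and changed sign with an array left out ranged from -2.74 to 0.32 for Cd3e and from -1.95 to 0.43 for Lep. The medians of lists ranged from -0.45 to 0.010 for basal and myoepithelial, from -0.30 to 0.088 for hormone-sensing and from -0.15 to 0.38 for plasma cell markers. The median of plasma cell markers was -0.018 with the 75th percentile filter, and that of red blood cell genes -0.0012 with no filter. Centred on epithelial markers, medians turned to 0.18 for brown adipocyte, 0.22 for fatty acid, 0.26 for hormone-sensing, 0.15 for alveolar regulator, 0.15 for basal, 0.10 for STAT family, 0.11 for STAT5 target and 0.037 for B cell lists and for Blnk. This setting moves all genes alike, to a median of 0.39, so small negative medians change sign by construction and say nothing about these lists. No paired analysis was possible because the labels give no replicate numbers shared between genotypes.

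Without detection calls, differences of dim probe sets are limited by an unknown background.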

Other observations

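All genes and lists of the next 2 paragraphs, and all tests of explanations except that of the authors' scaling, were chosen after the results were seen. Of 12 tested clock genes driven by E-box or D-box elements, 4 rose and 8 did not pass, with a median log2 difference of 1.09, and of 3 clock genes of the opposite phase 0 passed, with a median of -0.71. As these genes were put together after their values were seen, no test of them as a group is given. Per1 rose by 1.40 (limma adjusted p = 0.0308), Per3 by 1.38 (adjusted p = 0.0265), Nr1d2 by 1.33 (adjusted p = 0.0423) and Tef by 1.04 (adjusted p = 0.0365). Dbp gave 2.24 (adjusted p = 0.0586) and Per2 1.58 (adjusted p = 0.0765). Arntl, among the latter, gave -1.21 (adjusted p = 0.0610), with 438 and 389 on the WT and 133 and 215 on the KO arrays. All 4 calls were lost without WT replicate 1, and those of Per1, Per3 and Tef also without WT replicate 2. All 4 were lost with no filter, those of Nr1d2 and Tef with no trend and with the mean of all probe sets, and that of Nr1d2 with the 75th percentile filter. The labels give no hour of collection.

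Slc12a2, the sodium, potassium and chloride cotransporter, rose by 2.48 (limma adjusted p = 0.000553), from 2489 ± 8.98 to 13941 ± 277 (SD, n = 2), and the water channel gene Aqp5 rose by 2.24 (adjusted p = 0.00231). Both kept their call in every setting. Stc2, a secreted glycoprotein, rose by 2.06 (adjusted p = 0.00359), the iodide transporter gene Slc5a5 by 2.08 (adjusted p = 0.0324), Foxi1, a regulator of ion-transporting cells, by 1.78 (adjusted p = 0.0265) and Scnn1a, a sodium channel subunit, by 1.10 (adjusted p = 0.0369). Lgr6, a receptor for R-spondins, fell by 1.96 (adjusted p = 0.0154), the homeobox genes Irx3 and Irx5 by 1.54 (adjusted p = 0.0197) and 1.55 (adjusted p = 0.0178), and Id4 by 1.54 (adjusted p = 0.0427). Each of these 8 genes lost its call without WT replicate 2, as did Slc5a5, Scnn1a, Irx3, Irx5 and Id4 without WT replicate 1 and Scnn1a without KO replicate 1. All but Stc2 lost it with no filter, Irx3, Irx5 and Id4 centred on epithelial markers, Scnn1a and Id4 with no trend, and Id4 with the 75th percentile filter. Among 180 groups of genes sharing a symbol stem, the 9 Mcm genes had a median of -0.89 (camera adjusted p = 9.70e-05) and the 18 Nup genes, of nuclear pores, -0.32 (adjusted p = 0.00204). Abca (0.39, adjusted p = 0.0279) and Akr genes (0.39, adjusted p = 0.0495) were higher, and Exosc (-0.34) and Rrp genes (-0.37, adjusted p = 0.0495 for both) lower. With an estimated correlation the adjusted p = 0.981 for all 6 groups.

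The signals of Stat5a and Stat5b were higher on KO replicate 1 than on KO replicate 2. The gap was 0.58 to 1.08 on the log2 scale over 4 probe sets. As a share of WT these signals lay far above Csn1s1, Csn1s2a and Csn2. KO replicate 2 was taken as fully deleted and the signal lost there as epithelial. Epithelial cells that kept STAT5 in KO replicate 1 would then be 43.8% to 73.7% of the epithelium over the 4 probe sets. Among Csn1s1, Csn1s2a and Csn2, the highest there stood at 2.37% of WT. This argues against such a share only among cells that make these caseins. Csn3 was not part of this check and stood far higher. Its signals were 2687 on KO replicate 1 and 3256 on KO replicate 2, against a WT mean of 7205. The caseins of the check cannot show whether epithelial cells that make none of them kept STAT5, so that stays open. More of another cell type in KO replicate 1 cannot be told apart from other causes, since the largest difference between the KO arrays among 6 lists of other cell types, 0.82 for skeletal muscle, lies within the range of the Stat5 probe sets. A transcript that is still made from the deleted gene stays open and was not tested, because the deleted part is not given.

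The fall of cell cycle genes exceeded that of general epithelial markers in each pair of a KO with a WT array. The difference of the medians ran from -1.15 to -0.58 over the 4 pairs, with an SD of 0.26. Each array stands in 2 of the pairs, so they are not independent and the SD is no measure of error. If the median of epithelial markers follows the share of epithelium, these 4 arrays argue against a lower share as the whole cause. Members of that list ran from -1.78 for Ehf to 1.02 for Krt7, so its median is a rough gauge. The median of cell cycle genes was still -1.30 under the less favourable of quantile normalization and median centring, against -1.38 as deposited. The array medians, 121 to 131, allowed only a small shift, so this check could hardly fail and leaves the authors' scaling open. Centred on epithelial markers the median was -0.98. An effect of the genotype on cell division and a change in the mix of epithelial cells stay open and were not tested.

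H2-Ea, an MHC class II chain, stood at 3391 on WT replicate 1, at 62.5 on WT replicate 2 and at 33.8 and 26 on the KO arrays. More antigen-presenting cells in WT replicate 1 are argued against, since no other class II gene was higher there by more than 0.50 on the log2 scale, against 5.44 for H2-Ea. A sequence variant under a single probe set is argued against by the other H2-Ea probe set, which differed by 5.21. A difference in mouse background between the animals could leave this pattern and stays open and untested, as the labels name no strain. It is likewise open for Ifi202b and for the rises of a and Trim34a.

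In all, 12 probe sets with 1 gene differed at least 8-fold between the arrays of a genotype with a signal of 400 or more on the brighter, 3 in WT and 9 in KO. Ifi202b, an interferon-inducible gene, stood at 484 and 6.01 on the WT arrays and at 919 and 896 on the KO arrays. Gdpd3 stood at 2132 and 110 and the basal keratin gene Krt15 at 201 and 2395 on KO replicates 1 and 2. Pdxdc1 stood at 1370 and 26.2 there, while the median difference of its other 3 probe sets was -0.85.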
